A study of Mus musculus with 4 samples.

How the data were processed

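Mouse CD8 T cells from B16-OVA tumours were measured by droplet single-cell RNA sequencing with the 10x Genomics 5' v2 kit, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 7.0.1 on the mm10 build, per the submitters' processing notes. The gene annotation behind them is not given in the sources used here. Each matrix also held the hashtag counts, as 4 features of type Custom, of which the last was nearly empty (3 counts in each library). The accompanying deposited lists hold only names, of features and of barcodes, and a deposited hashtag table pairs 3 hashtag antibodies with sorted populations. The 2 hashtag oligo samples have no files of their own. Hashtags were matched to the Custom features by the final digit of their names, a match no source states. Gene coordinates are from GENCODE vM21 on GRCm38, the same assembly as mm10, and 32285 genes were in each matrix.

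The labels name wild-type and Nr4a cells, but the hashtag table names CD8, TAM- and TAM+ populations. The planned comparison of Nr4a with wild-type cells was therefore made as TAM+-labelled against TAM-. TAM- against CD8 was added after the hashtag table was read. TAM+ against CD8 was fitted as well and is not reported. The treatment label reads tamoxifen for every sample, so tamoxifen status was taken from the hashtag table and the protocols alone. The protocol adds Lag3 to the gate of the TAM- cells, which the hashtag table leaves out.

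The 2 libraries shared 2805 barcodes, and these were removed from library 2, a choice made after the data were seen. Each hashtag was called by a mixture of 2 normal components on log counts, which put the thresholds at 47, 179 and 58 counts in library 1 and at 17, 90 and 12 in library 2 (CD8, TAM-, TAM+). Barcodes with exactly 1 hashtag numbered 4389 and 2429, those with several 335 and 188, and those with none 33 and 18. Only barcodes with 1 hashtag were used, which removes doublets between populations. Cells needed at least 500 genes and at most 10% mitochondrial UMIs, and 70 and 48 failed. Scrublet called only 4 and 1 doublets, so it did not work here, and doublets within a population remain. This left 4319 and 2380 cells.

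Scrublet was run in scanpy 1.11.5. Cells were clustered with leidenalg 0.10.2 on a graph of shared neighbours (igraph, numpy 2.4.6, scikit-learn 1.9.0, scipy 1.17.1). The clustering used 2000 variable genes without receptor variable segments, ribosomal and mitochondrial genes, Nr4a1, Nr4a2 and Nr4a3. The settings were 30 principal components, 20 neighbours, resolution 0.6 and random seed 1. Clusters were named from fixed markers. A marker counted when its log2 fold over the other cells was at least 0.5 (prior 5 CPM) with a UMI in at least 20% of the cluster's cells, and a name needed 3. Lineage markers needed a log2 fold of 2. A name also needed a gene of its own among the cluster's top 10, a rule set after the data were seen. It left unnamed the cluster led by Serpinb9b and Spp1, which had 5 cycling markers, and the shallow cluster, which had 3 exhaustion markers. With doublets kept, the best class of the cluster led by Serpinb9b was exhaustion, with 5 markers, and it stayed unnamed too. In the main clustering these 2 clusters held the following shares. The cluster led by Serpinb9b held 3.09% and 3.48% of CD8, 38.6% and 32.8% of TAM- and 2.85% and 3.95% of TAM+-labelled cells. The shallow cluster held 0.924% and 1.31%, 5.33% and 8.99%, and 2.22% and 0.658%.

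T cell counts were summed per library and population, since cells are not replicates. Sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The SE of a log2 fold change is its size divided by the square root of the F statistic. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, where at least 3 members were tested. So few sums leave very few residual degrees of freedom for that estimate. The variant therefore has little power, and a list that misses it is neither refuted nor backed by it. In the lists' results the first number after the counts is camera's adjusted p, and the one named estimated is that with an estimated correlation. The lists were Nr4a family, stem-like, terminal exhaustion and inhibitory receptors, AP-1 and early activation, cytotoxic effector, NK-receptor and short-lived effector, tissue residency, cell cycle, interferon response, glycolysis and hypoxia, survival and apoptosis, dissociation and heat-shock stress, CD8 T cell identity and OT-I receptor. Lists of other cells were CD4 and regulatory T cell, myeloid, dendritic cell, B cell, NK cell, B16 melanoma, stroma and red blood cell. Counts of T cell lists leave out the Nr4a family and OT-I receptor lists, which are given apart.

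For the Tcf7 comparison a cell was Tcf7-detected when it kept a Tcf7 UMI after random thinning to 2000 UMIs, and shallower cells were left out. The sums used unthinned counts, with the library as a block, and Tcf7 itself was left out. Undetected cells include expressing cells whose Tcf7 was missed. Shares carry exact Clopper-Pearson 95% intervals and were compared by two-sided exact permutation tests. For the fold of Xist a count of 0 was set to a floor of 3 counts, and elsewhere counts of 0 carry the upper limit of the exact Poisson or Clopper-Pearson 95% interval. Reads of near-identical genes (granzymes Gzmc to Gzmf, Hspa1a and Hspa1b, Bcl2a1b and Bcl2a1d, histones) may be split by the counting, so values of single members are uncertain.

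Both populations of a library come from the same pool, so replicate numbers pair the samples. Across 5650 genes, the library differences correlated at 0.195 between TAM+ and TAM- and at 0.521 between TAM- and CD8. The planned fits of these populations had no block, and the fit with the library as a block is given where it changed the call of a list or of a gene named by the rule below. Nothing in the labels says that the libraries came from separate animals. Without a block the p-values therefore measure the spread between libraries, which may be technical. With the library as a block, as in the Tcf7 comparison, they measure how alike the difference was in the 2 libraries. Per-cell depth differed between populations, with median T cell UMIs of 5341.5 and 4124 in CD8, 10475 and 7714 in TAM-, and 6829.5 and 6036 in TAM+-labelled cells.

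Named genes were fixed as Nr4a1, Nr4a2 and Nr4a3, the 8 highest and 8 lowest called genes with a mean of at least 20 CPM and the same direction in each library, and the 3 members with the smallest p of each T cell list. For the libraries they were the 5 highest and 5 lowest ratios among genes with at least 200 UMIs in each. Variable segments and predicted genes were counted but not named, and 2 further genes chosen by the rule are not reported here. Tcf7 in the comparisons of populations, and single genes of the lists of other cells, were named after their values were seen. The lists, the naming rule, the tests, the cell filters and the clustering settings were fixed before the data were examined.

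Alternatives fixed before the data were examined were DESeq2 1.42.0, library size as the only scaling, no filter on low counts, all deposited barcodes, a strict filter (1000 genes, 5% mitochondrial UMIs), doublets kept, other lineages kept, a hashtag rule of 70% of at least 10 counts, the block, other resolutions and thinning depths, unthinned Tcf7 calls, clusters named cycling left out for the Tcf7 comparison, and leaving out each library. The cluster led by Serpinb9b stayed in there with its 5 cycling markers, so that alternative still holds cycling cells. Every alternative for TAM- against CD8 was added afterwards, as that comparison was. Others added after seeing the data were shared barcodes kept, every cell thinned to 2000 UMIs, cells with Y-linked transcripts and no Xist, clusters named cycling left out in the comparisons of populations, the shallow cluster left out, the highest 6% of Scrublet scores left out, the Tcf7 comparison within populations, and 10 further thinning draws. Figures were drawn with matplotlib 3.10.9.

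The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from the more abundant genes alone, so the recovery given here does not cover genes with low counts. edgeR recovered 88% and 100% in the design of TAM+-labelled against TAM- (10403 genes), and all changed genes in those of TAM- against CD8 (11237 genes) and of Tcf7 (11112 genes). It called 8, 6 and 19 unchanged genes. DESeq2 recovered 63% and 97%, 100% and 100%, and 87% and 100%. The simulated dispersion was held at 0.005 or more, while the fitted common dispersions were 0.00433, 0.00361 and 0.000369.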

Results

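Single-cell RNA was measured in mouse CD8 T cells from B16-OVA tumours, a melanoma line that carries ovalbumin. The cells had the OT-I receptor for ovalbumin, floxed Nr4a1 and Nr4a2, and a tdTomato reporter. They came from Rag2-deficient recipients, which have no T cells of their own. The protocols give 3 weeks after tumour injection, but PD1+Tim3+ cells isolated on day 21 went into second recipients that then received tumours, so the populations need not share hosts or time. Each of the 2 libraries, labelled as replicates, pooled 3 sorted populations, each with its own hashtag: CD8 cells, PD1+Tim3+ cells named TAM-, and PD1+Tim3+ cells named TAM+. Per the labels' protocols, TAM- cells were taken before tamoxifen and TAM+ cells were tdTomato-positive ones taken afterwards, when Cre was to have removed the floxed genes. Library 1 held 4757 barcodes and 43360791 UMIs, and library 2 held 5440 barcodes and 27756351 UMIs. Of these, 2805 barcodes occurred in both libraries and were kept in library 1 alone, leaving 2635 in library 2. The T cells numbered 2162 and 1147 (CD8), 1834 and 1077 (TAM-), and 168 and 63 (TAM+) in libraries 1 and 2. Their summed counts ranged from 427730 UMIs for TAM+ in library 2 to 21178120 for TAM- in library 1.

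**Figure D1:**
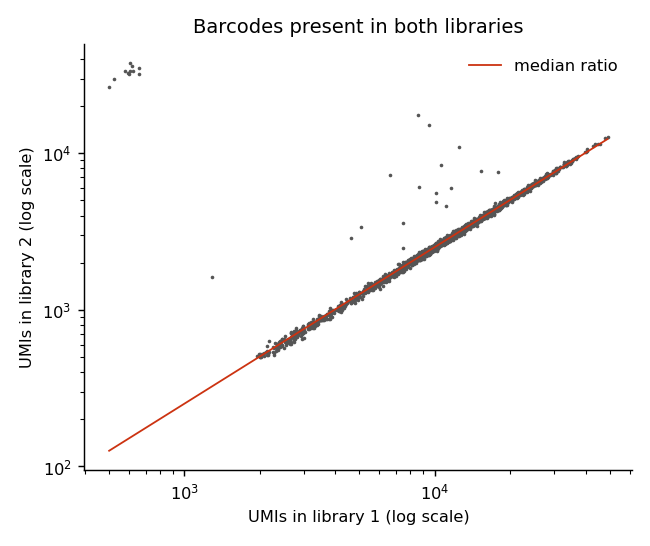
UMIs in library 2 against UMIs in library 1 (both axes logarithmic) for the 2805 barcodes present in both, each a point, with a line at the median ratio. Of these barcodes, 2772 lie within 10% of the median ratio of 25.2%, and 15 had more UMIs in library 2.

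Clustering the 4319 and 2380 cells of libraries 1 and 2 together gave 7 T cell clusters and 4 of other lineages. A cluster of 1973 cells, led by Neurl3, Il7r, Emb and Tcf7, was progenitor-exhausted-like, a name for cells that keep self-renewal genes. It held 31.0% of T cells in library 1 (95% Clopper-Pearson interval 29.6 to 32.4) and 29.9% in library 2 (28.0 to 31.8). The cycling-like cells formed a cluster of 1117, led by Ccnb1ip1, Mybl2 and Cdc6, and another of 737, led by histone genes, Cenpf and Cdc20. Together they made up 28.1% (26.8 to 29.5) and 29.8% (28.0 to 31.7) of T cells. The intervals leave out the choice of resolution, as this share was 48.0% and 47.8% at resolution 0.3 and 3.75% and 3.37% at 1.0. A terminally exhausted-like cluster of 203 cells was led by Gzmk, Igkc, Cdkn2a, Entpd1 and Prf1, and held 3.51% (2.97 to 4.11) and 2.49% (1.89 to 3.22). The 3 remaining T cell clusters stayed unnamed and held 37.4% (35.9 to 38.9) and 37.8% (35.8 to 39.8). They were led by Serpinb9b, Spp1 and Cd81 (1185 cells), by Utf1, Ccl4 and Xcl1 (998 cells), and by St6galnac3, Chst11 and Dock2 in shallow cells (238 cells, median 1980 UMIs). The terminally exhausted-like cluster consisted of 173 TAM+-labelled, 26 TAM- and 4 CD8 cells. No cluster met the markers of interferon-responding or NK-receptor effector cells.

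**Figure D2:**
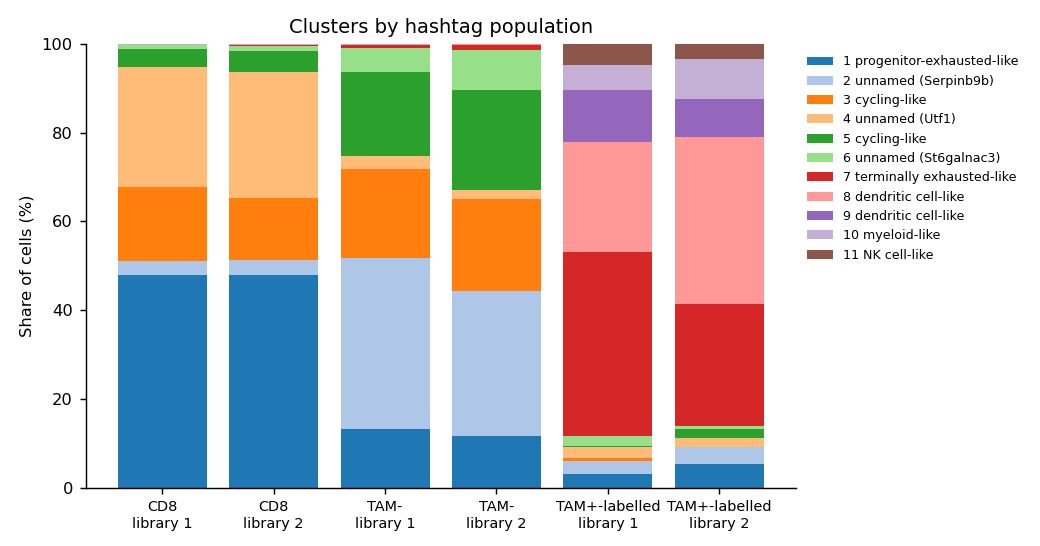
Percent of the cells of each population and library (vertical axis) that fell in each cluster, as stacked bars for CD8, TAM- and TAM+-labelled cells of each library, without intervals. The terminally exhausted-like cluster held 41.5% and 27.6% of TAM+-labelled cells in libraries 1 and 2, and 0.707% and 1.20% of TAM- cells.

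Cells of other lineages were found mainly under the TAM+ hashtag. Of TAM+-labelled cells, 46.8% (148 of 316, 41.2 to 52.5) in library 1 and 58.6% (89 of 152, 50.3 to 66.5) in library 2 lay in dendritic, myeloid or NK clusters. These shares were 0.139% and 0.174% of CD8 cells and 0.218% and 0.185% of TAM- cells. The larger dendritic cluster (136 cells) was led by Ly6d and Siglech, as in plasmacytoid dendritic cells, and a smaller one (50 cells) by H2-Ab1 and Plbd1. The myeloid cluster (37 cells) was led by Lyz2 and Cxcl2, and the NK cluster (25 cells) by Klra8, Klra7 and Ncr1. These cells were left out of the comparisons of T cells.

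The T cell sums of the libraries differed little from each other, which describes the replicates and was not tested. Across 7054 genes with at least 200 UMIs in each library, log2 CPM (counts scaled to the same total) correlated at 0.996, over genes and not over independent replicates. The ratio exceeded 1.5-fold for 48 genes and 2-fold for 8. Library 2 held more of the histone genes Hist1h2af (ratio 3.58, 95% Poisson interval 3.08 to 4.16), Hist1h2ak (2.81, 2.52 to 3.13), Hist4h4 (2.21, 1.85 to 2.64) and Hist2h4 (2.05, 1.73 to 2.42), and of Zc3h7a (2.15, 2.05 to 2.25). It held less of Pde1c (0.515, 0.440 to 0.601), Rpl9-ps6 (0.560, 0.483 to 0.647), Rpl10-ps3 (0.579, 0.509 to 0.656), Psme2b (0.590, 0.512 to 0.677) and Ckb (0.624, 0.549 to 0.709). Reads of histone copies and of the pseudogenes Rpl9-ps6 and Rpl10-ps3 can be shared with near-identical sequences, so these ratios are uncertain.

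The first comparison set TAM+-labelled against TAM- T cells. Tamoxifen and the sort gate change with the label, and the hosts and the time may. The comparison therefore does not isolate the loss of Nr4a1 and Nr4a2. Of TAM- T cells, 13 of 1834 and 13 of 1077 lay in the terminally exhausted-like cluster. The unnamed cluster led by Serpinb9b held 38.6% and 32.8% of TAM- cells. With doublets kept, the cluster led by Serpinb9b had 5 exhaustion markers: Havcr2, Rgs16, Prf1, Gzmb and Ccl3. The counts above are thus of the named cluster alone, and not of all TAM- cells with exhaustion genes. The floxed genes came first. Nr4a1 (chromosome 15, 101254269 to 101274795, mm10) stood at 281 and 180.0 CPM in the TAM+-labelled sums of libraries 1 and 2, against 237 and 264 CPM in TAM-. Its log2 fold change was -0.07 (SE 0.14, edgeR adjusted p = 0.777), and the libraries went opposite ways. Nr4a2 (chromosome 2, 57106830 to 57124003) was higher, at 974 and 1003 CPM against 667 and 654 (log2 0.53, SE 0.10, edgeR adjusted p = 0.000518), but not when other lineages were kept (-0.10). The 5' tags may lie outside the deleted part and the floxed exons are not given, so these totals check nothing about the deletion, and the cells are called TAM+-labelled throughout. The third family member, Nr4a3 (chromosome 4, 48045153 to 48086447), fell from 156 ± 5.84 to 75.7 ± 2.09 CPM (SD, n = 2 libraries; log2 -1.10, SE 0.13, edgeR adjusted p = 6.81e-06). As a list the 3 were not called (camera adjusted p = 0.843, adjusted p = 0.860 with an estimated correlation).

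Among the genes named here, several effector and exhaustion genes were higher in TAM+-labelled T cells and several stem-like genes were lower. Gzmk, a granzyme (chromosome 13, 113171608 to 113225908), rose from 11.1 ± 0.737 to 513 ± 11.2 CPM (SD, n = 2; log2 5.47, SE 0.12, edgeR adjusted p = 5.83e-17). The perforin gene Prf1 rose from 93.2 ± 2.55 to 904 ± 217 CPM (log2 3.26, SE 0.13, edgeR adjusted p = 8.18e-13), and the chemokine gene Ccl5 from 461 ± 42.5 to 4371 ± 366 CPM (log2 3.20, SE 0.11, edgeR adjusted p = 5.02e-14). Pdcd1, which encodes PD1, rose by log2 2.40 (SE 0.11) to 494 ± 54.6 CPM, Tox by 2.22 (SE 0.11) to 444 ± 3.35 CPM, and the ectonucleotidase gene Entpd1 by 3.81 (SE 0.16) to 143 ± 33.1 CPM. Tcf7 (chromosome 11, 52252371 to 52283014), which encodes TCF1, fell from 82.1 to 16.3 CPM in library 1 and from 95.1 to 32.7 in library 2 (log2 -2.16, SE 0.22, edgeR adjusted p = 8.56e-07). The lymph node homing gene Ccr7 fell by log2 -3.48 (SE 0.22), by -4.14 in library 1 and by -2.69 in library 2, and the chromatin and transcription factor genes Satb1 and Bach2 by -3.76 (SE 0.19) and -3.23 (SE 0.19). In all, 890 genes were higher and 1060 lower among 10650 tested.

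The ranking takes called genes with a mean of at least 20 CPM and the same direction in each library. The other genes at its top were Igkc (log2 8.37), Cdkn2a (4.26), Gldc (4.16), Il1r2 (3.73), Ccl9 (3.59) and Mt3 (3.40). Igkc stood at log2 8.23 in library 1 alone and 6.73 in library 2 alone, and Ccl9 at 3.75 and 2.48. Igkc encodes an immunoglobulin light chain and stood at 431 CPM in the Siglech-led dendritic cluster of the same hashtag. At the bottom were Ifitm2 (-4.24), the cytokine genes Tnfsf8 (-3.55) and Csf2 (-3.53), and Xist (chromosome X, 103460366 to 103483254), the RNA of the silenced X chromosome. Xist had 1877 UMIs in TAM- and 0 in TAM+-labelled T cells, so it was at least 37.5-fold lower with the floor of 3 counts taken over the group. The OT-I beta segment Trbv12-1 fell from a mean of 1604 to 703 CPM (n = 2, log2 -1.27, SE 0.11, edgeR adjusted p = 1.50e-07), while its share of all Trbv UMIs was 99.9% in both populations. The other OT-I segment, Trav14-1, was higher at low counts (log2 2.62, SE 0.67, edgeR adjusted p = 0.00964).

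Of the fixed gene lists, 6 of 12 T cell lists were called between TAM+-labelled and TAM- cells. The stem-like list had 12 lower and 0 higher genes among 16 tested (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.72e-09). The list of AP-1 and early activation genes, which report recent receptor signals, had 11 lower and 1 higher of 14 (11 and 1 adjusted over the list alone; 8.11e-06): Fos (-1.11) and Nfkbid (-1.81, from -2.15 in library 1 to -1.22 in library 2) were lower and Batf (2.62) higher. The cell cycle list had 8 lower of 16 (10 adjusted over the list alone; 2.88e-06), among them Mki67 (-1.16), Top2a (-0.88) and Stmn1 (-0.71). The survival and apoptosis list had 4 lower of 8 (6 lower and 1 higher adjusted over the list alone; 0.00674), among them the pro-apoptotic Bcl2l11 (-2.18), Bcl2a1b (-0.85) and Bcl2 (-0.58). The cytotoxic effector list had 11 higher and 2 lower of 15 (11 and 3 adjusted over the list alone; 1.25e-09). The list of terminal exhaustion and inhibitory receptors had 8 higher and 3 lower of 17 (8 and 3 adjusted over the list alone; 2.33e-04). All 6 had camera adjusted p = 0.280 with an estimated correlation. None of the 6 calls held under it, but with so few sums that variant has little power and cannot decide on them.

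The remaining T cell lists were not called. The NK-receptor list had 2 higher and 3 lower of 10 (camera adjusted p = 0.279; 3 and 4 adjusted over the list alone, adjusted p = 0.519 with an estimated correlation): Klrg1 (4.87) was higher, and Klrd1 (-1.32) and Zeb2 (-1.61) were lower. Tissue residency had 3 higher and 3 lower of 7 (0.647; 3 and 3 over the list alone, estimated 0.693), with Prdm1 (2.67) and Cxcr6 (1.31) higher and Cd69 (-1.63) lower; its median was -0.56 though the test pointed up. Interferon response had 2 lower of 10, Usp18 (-1.21) and Isg15 (-0.61), with Ifit2 not passing (0.348; 2 over the list alone, estimated 0.693). Glycolysis and hypoxia had only Bnip3 (-0.70, from -0.63 in library 1 to -1.50 in library 2) lower of 11, while Tpi1 and Pgk1 passed only with the library as a block (edgeR adjusted p = 0.0170 and 0.0222) (list 0.647; 0 over the list alone, estimated 0.693). Heat-shock stress had Hsph1 (0.79) higher of 7, while Hsp90aa1 and Hspa8 passed only with the block (edgeR adjusted p = 0.0399 and 0.0469) (list 0.581; 1 over the list alone, estimated 0.693). CD8 identity had 4 higher, Cd2 (0.52) and Cd3g (0.38) among them, and 1 lower, Cd8b1 (-0.68), of 10 (0.184; 5 and 1 over the list alone, estimated 0.607).

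Few markers of other cell types were higher in TAM+-labelled T cells once the other lineages were removed. Of 6 myeloid genes tested, Lyz2 was lower (6.89 CPM in TAM- and 0 in TAM+-labelled cells, with an exact Poisson 95% upper limit of 2.00) and 5 did not pass (camera adjusted p = 0.647; 1 lower adjusted over the list alone, adjusted p = 0.693 with an estimated correlation). Of 3 dendritic genes, H2-Ab1 (-1.24) and Cd74 (-0.49) were lower (0.0658; 3 lower over the list alone, estimated 0.361). The CD4 and regulatory T cell list had 0 of 3 called (0.266; 1 lower over the list alone, estimated 0.519). Among lists with fewer than 3 tested genes, Cd79b of the B cell list was lower (-2.88, edgeR adjusted p = 0.0461; Ighm did not pass), Eomes of the NK list was higher (0.92, 6.64e-05) and Pecam1 of the stroma list was lower (-1.51, 8.77e-04). No B16 melanoma or red blood cell gene was abundant enough to be tested.

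The size of the difference depended on the counting, since DESeq2 called 474 genes higher and 476 lower, cells thinned to the same depth gave 250 and 327, and shared barcodes kept in library 2 gave 1458 and 1663. Keeping the other lineages gave 1972 higher genes and reversed 8 of the 50 named ones: Nr4a2, Ifitm2, Fos, Zeb2, Usp18, Isg15, Cd2 and Cd3g.

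**Figure D3:**
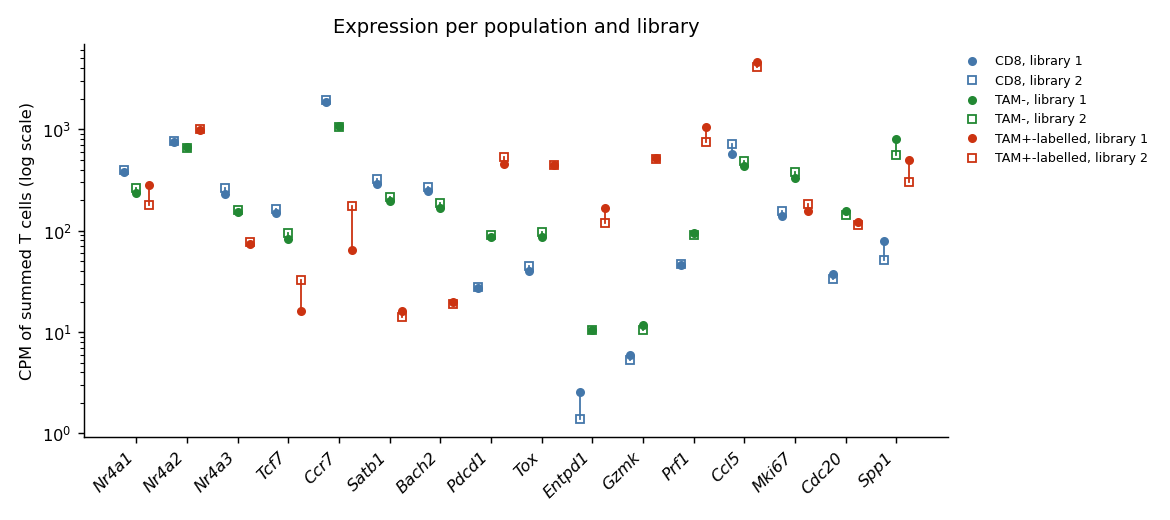
CPM (logarithmic vertical axis) of named genes in the T cell sums of CD8, TAM- and TAM+-labelled cells, with circles for library 1 and squares for library 2. Gzmk stood at 11.1 CPM on average in TAM- and 513 in TAM+-labelled cells, and Ccr7 at 1061 and 120.2 CPM.

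The share of stem-like cells addressed whether the labelled cells held more TCF1-expressing precursors. The progenitor-exhausted-like cluster held 5.95% (95% Clopper-Pearson interval 2.89 to 10.7) and 12.7% (5.65 to 23.5) of TAM+-labelled T cells, and 13.2% (11.7 to 14.9) and 11.6% (9.75 to 13.7) of TAM- T cells. The mean difference was -3.10 percentage points (SD 5.93, n = 2 libraries, two-sided exact permutation p = 0.6667), less than its spread, and its sign rested on the library: -7.30 in library 1 and 1.09 in library 2. The sign also turned with the clustering, with a mean of 0.68 at resolution 0.3 and 2.85 at 1.0, where the libraries gave 0.83 and 4.86. With 2 libraries per group the smallest p the test allows is 0.3333. Tcf7, which helps to define that cluster, differed between the populations, so the share and the Tcf7 level are not separate evidence. The unnamed clusters held 14.3% and 15.9% of TAM+-labelled and 46.8% and 43.9% of TAM- T cells.

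After every cell was thinned to 2000 UMIs, a Tcf7 UMI was seen in 27.1% (25.2 to 29.1) and 27.1% (24.5 to 29.9) of CD8, 16% (284 of 1775, 14.3 to 17.8) and 16.04% (13.8 to 18.5) of TAM-, and 4.90% (1.99 to 9.83, 7 of 143) and 5.56% (1.16 to 15.4, 3 of 54) of TAM+-labelled T cells in libraries 1 and 2. Over all T cells the shares were 21.4% and 21.3%. In the dendritic and myeloid cells, where Tcf7 was taken as background, they were 1.54% (0.187 to 5.45) and 1.49% (0.0378 to 8.04), which overlaps the TAM+-labelled shares. Median depths were 5341.5 and 4124 UMIs (CD8), 10475 and 7714 (TAM-), 6829.5 and 6036 (TAM+-labelled) and 4096 and 2790.5 (dendritic and myeloid). The mean difference of TAM+-labelled minus TAM- was -10.8 points (SD 0.439, n = 2, two-sided exact permutation p = 0.3333, the smallest it can give). Without thinning the shares were 51.8% and 46.0% (CD8), 46.5% and 41.2% (TAM-), 8.93% and 14.3% (TAM+-labelled), 47.7% and 42.9% (all T cells) and 6.57% and 4.65% (background). Cells too shallow to thin numbered 88 and 93, 59 and 67, and 25 and 9 in the 3 T cell populations, and 7 and 19 in the background.

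**Figure D4:**
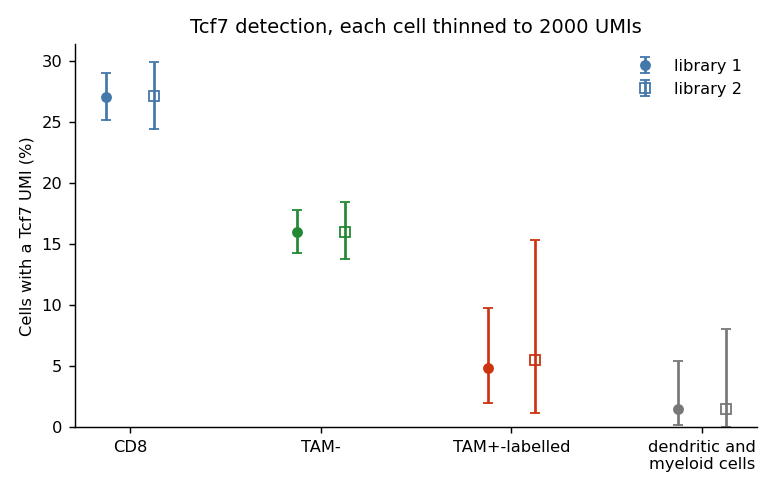
Percent of cells with a Tcf7 UMI after thinning every cell to 2000 UMIs (vertical axis) in CD8, TAM- and TAM+-labelled T cells and in dendritic and myeloid cells, with circles for library 1, squares for library 2 and 95% Clopper-Pearson intervals. The CD8 points lie at 27.1% in each library, the TAM- points at 16% and 16.04%, and the TAM+-labelled intervals overlap those of the dendritic and myeloid cells.

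The comparison of TAM- with CD8 T cells described cells sorted for PD1 and Tim3 against the whole CD8 gate, for which the hashtag table names no tamoxifen state. TAM- cells had more of the osteopontin gene Spp1, which rose from 64.6 ± 19.2 to 674 ± 171 CPM (SD, n = 2 libraries; log2 3.20, SE 0.18, edgeR adjusted p = 7.94e-08), and of Gzmb, from 289.9 ± 4.09 to 856 ± 44.3 CPM (log2 1.42, SE 0.07, edgeR adjusted p = 4.46e-08). Pdcd1 rose from 27.6 ± 0.277 to 89.0 ± 3.28 CPM (log2 1.54, SE 0.08, edgeR adjusted p = 6.66e-08), and Tox by log2 1.00 (SE 0.09). Pdcd1 encodes PD1, on which the TAM- cells were sorted, so the gate may set its rise. Tcf7 fell from 157 ± 8.79 to 88.6 ± 9.19 CPM (log2 -0.98, SE 0.08, edgeR adjusted p = 2.23e-06), and the interleukin-7 receptor gene Il7r from 146 ± 4.68 to 63.8 ± 0.200 CPM (log2 -1.33, SE 0.08, edgeR adjusted p = 7.94e-08). Nr4a1 (-0.78, SE 0.07), Nr4a2 (-0.35, SE 0.07) and Nr4a3 (-0.81, SE 0.08) were each lower in TAM- cells, in every scaling tried (camera adjusted p = 4.31e-04, adjusted p = 0.256 with an estimated correlation). Heat-shock genes, which can report handling stress, were lower as well, 7 of 8.

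In all, 1484 genes were higher and 1490 lower in TAM- among 11592 tested. The ranking again takes called genes with a mean of at least 20 CPM and the same direction in each library. Its top held the granzyme inhibitor gene Serpinb9b (3.30), the granzymes Gzmc (2.83) and Gzma (2.11), the tetraspanin gene Cd81 (2.71), and the mitotic genes Plk1 (1.98), Pimreg (1.97) and Cdc20 (1.93). Its bottom held Pmepa1 (-1.67), Cebpb (-1.65), Dusp10 (-1.64), Neurl3 (-1.62), Fosl2 (-1.55), Emb (-1.53), Lilr4b (-1.46) and Cxcr4 (-1.45). With the library as a block, 2408 genes were higher and 2425 lower. Library size alone as the scaling called 2878 higher and 891 lower, 76.4% higher against 49.9%, as it moved the median of all genes to 0.14 from -0.0048.

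Between TAM- and CD8 cells 9 of 12 T cell lists were called, besides the Nr4a family list given above. The cell cycle list had 13 higher of 16 (14 adjusted over the list alone; camera adjusted p = 2.01e-17, adjusted p = 0.252 with an estimated correlation), led by Ube2c (1.75) and Cdk1 (1.36). The stem-like list had 15 lower of 16 (15 over the list alone; 1.42e-14, estimated 0.252), among them Ccr7 (-0.98) and S1pr1 (-2.27). Heat-shock stress had 7 lower of 8 (7 over the list alone; 5.09e-07, estimated 0.252), with the near-identical pair Hspa1a (-3.23) and Hspa1b (-2.48), and Hsph1 (-0.80). AP-1 and early activation had 8 lower and 2 higher of 14 (10 and 2 over the list alone; 1.54e-04, estimated 0.317), among them Nfkbid (-1.16) and Egr1 (-1.14). The cytotoxic effector list had 8 higher and 3 lower of 15 (9 and 3 over the list alone; 4.31e-04, estimated 0.317), with Gzmf at 5.55, a granzyme whose reads can be shared with its neighbours. Glycolysis and hypoxia had 8 higher and 2 lower of 11 (8 and 2 over the list alone; 4.31e-04, estimated 0.256), among them Pgk1 (0.58), Eno1 (0.77) and Tpi1 (0.61).

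The other called lists, 3 in number, had larger p-values. Of these, the terminal exhaustion list holds the genes of PD1, Tim3 and Lag3. TAM- cells were sorted on PD1 and Tim3, and on Lag3 per the protocol, so the gate may set part of that call. Terminal exhaustion had 6 higher and 1 lower of 16 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0139, adjusted p = 0.317 with an estimated correlation), with Entpd1 at 2.11. Survival and apoptosis had 4 lower of 8 (6 over the list alone; 0.0114, estimated 0.317): Bbc3 (-0.78), Mcl1 (-0.35) and Bcl2a1b (-0.37) were among them. Interferon response had 5 lower of 11 (7 over the list alone; 0.0101, estimated 0.317; 0.133 with the library as a block), among them Ifit3 (-1.36), Isg20 (-0.52) and Ifit1 (-1.14). Tissue residency was not called, with 4 lower and 2 higher of 8 (4 and 2 over the list alone; 0.102, estimated 0.317), but was with the block (0.0205): Cxcr6 (-1.08) and Rgs1 (-0.75) were lower and Prdm1 (2.20) higher. The NK-receptor list, with Cx3cr1 (0.91) higher and Klrc1 (-0.61) and Klrd1 (-0.25) lower, had 3 higher and 2 lower of 9 (3 and 2 over the list alone; 0.729, estimated 0.753). CD8 identity had Trac (-0.33) and Cd3e (-0.20) lower of 10, and Cd3d (-0.18) passed only with the block (edgeR adjusted p = 5.00e-12) (2 over the list alone; 0.270, estimated 0.408).

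The tested genes of the dendritic list, H2-Ab1, H2-Aa and Cd74, were higher in TAM- than in CD8 cells. Cd74 stood at 29.3 ± 11.7 CPM in CD8 and 105 ± 2.19 in TAM- cells, and all 3 dendritic genes were called (camera adjusted p = 8.78e-04; 3 adjusted over the list alone, adjusted p = 0.317 with an estimated correlation). Of 6 myeloid genes 4 were higher, C1qa, C1qb, C1qc and Lyz2, each under 7 CPM (0.0304; 4 over the list alone, estimated 0.385; 0.187 with the library as a block). Cd4 (2.22) and Ikzf2 (0.59) were higher and Cd40lg (-1.53) lower (0.406; 2 and 1 over the list alone, estimated 0.548). Of the shortest lists, Ighm (0.40) and Pmel (1.80, at 1.25 CPM) were higher and Cd79b (-0.76) lower, and Eomes, Pecam1, Trbv12-1 and Trav14-1 did not pass. No red blood cell gene was tested. DESeq2 called 781 genes higher and 816 lower, thinned cells gave 959 and 939, and cells with Y-linked transcripts and no Xist gave 952 higher.

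The last comparison asked which genes go with Tcf7, the marker of stem-like precursors, across all T cells. Both classes were split from the same pools, so with the library as a block the p-values leave out the spread between libraries. In Tcf7-detected against undetected cells, with the library as a block, Gzmb fell from 784 ± 63.0 to 309 ± 30.5 CPM (SD, n = 2 libraries; log2 -1.34, SE 0.03, edgeR adjusted p = 1.02e-28), and Ccl3 from 384 ± 65.6 to 106 ± 24.2 CPM (log2 -1.85, SE 0.04, edgeR adjusted p = 2.37e-28). Klf2, a factor for exit from tissue, rose from 70.9 ± 3.67 to 131 ± 16.8 CPM (log2 0.86, SE 0.06, edgeR adjusted p = 4.85e-14), and the adhesion gene Emb from 172 ± 3.88 to 292 ± 6.55 CPM (log2 0.77, SE 0.04, edgeR adjusted p = 1.45e-17). Nr4a1 (-0.24, SE 0.04) and Nr4a2 (-0.31, SE 0.03) were lower in Tcf7-detected cells, Nr4a1 only with the library as a block (edgeR adjusted p = 0.0973 without), and Nr4a3 did not pass (-0.01, SE 0.05, edgeR adjusted p = 0.927). As a list the 3 were lower (camera adjusted p = 0.00396, adjusted p = 0.543 with an estimated correlation). In all, 800 genes were higher and 994 lower among 11362 tested. This pools populations that differ in their Tcf7-detected share: within populations 484 were higher and 574 lower, and within TAM- alone 42 and 67.

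Among called genes with a mean of at least 20 CPM and the same direction in each library, others ranked highest. They were Arl5c (0.86), Sntb1 (0.84), Aff3 (0.83), Nsg2 (0.82), Scml4 (0.79) and Neurl3 (0.76). The lowest under the same rule were Serpinb9b (-3.05), Ccl1 (-1.90), Gzma (-1.78), Prf1 (-1.52), Spp1 (-1.51), Lgals3 (-1.46) and Gzmc (-1.43). Gzma stood at -1.34 in library 1 alone and -3.65 in library 2 alone, and Gzmc at -1.25 and -2.36. Within CD8 cells Prf1 did not pass (-0.21, edgeR adjusted p = 0.354), while within TAM- it stood at -1.29. Lgals3 was lower within both (-0.72 and -1.59). The OT-I segment Trbv12-1 was slightly higher (0.21) and Trav14-1 did not pass. The lists were tested over pooled populations alone, so the differing Tcf7-detected shares of the populations may enter their calls. Besides the Nr4a family list, 6 of 12 T cell lists were called. Of the genes named for these lists, Rrm2, Mcm3, Tyms, Ldha and Rsad2 did not pass without the block. Tyms also reversed with unthinned classes. The cytotoxic effector list had 13 lower of 15 (15 adjusted over the list alone; camera adjusted p = 1.24e-31, adjusted p = 0.528 with an estimated correlation), Ccl4 (-1.24) among them. The stem-like list without Tcf7 had 12 higher and 1 lower of 15 (12 and 1 over the list alone; 2.14e-14, estimated 0.528), with Satb1 (0.53) higher and the chemokine gene Xcl1 (-0.62) lower. Glycolysis and hypoxia had 8 lower of 11 (8 over the list alone; 3.66e-13, estimated 0.528), among them Tpi1 (-0.42), Pgk1 (-0.33) and Ldha (-0.24). Cell cycle had 7 lower of 16 (9 over the list alone; 1.76e-05, estimated 0.543), among them Rrm2 (-0.30), Mcm3 (-0.28) and Tyms (-0.26). Terminal exhaustion had 9 lower and 2 higher of 16 (9 and 3 over the list alone; 2.94e-05, estimated 0.528), among them Pdcd1 (-0.98), Tnfrsf9 (-0.52) and Rgs16 (-0.43). Interferon response had 5 higher of 11 (8 over the list alone; 2.30e-04, estimated 0.543), with Irf7 (0.43) and Rsad2 (1.39) among them, but Rsad2 was called in 1 of 10 further thinning draws and Irf7 in 9, and both reversed with unthinned classes.

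The other lists were not called between Tcf7-detected and undetected cells. Of the genes named for them, only Fcer1g, Tyrobp, Prdm1 and Hspa1a also passed without the block. Rgs1 and Cd2 reversed with unthinned classes, Rgs1 and Klrd1 in TAM- cells alone, and Junb with clusters named cycling left out. The NK-receptor list had 5 lower and 1 higher of 9 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0683, adjusted p = 0.543 with an estimated correlation; 0.00947 without the block), with Fcer1g (-1.43) and Tyrobp (-1.40) lower and Klrd1 (0.14) higher. AP-1 and early activation had 3 lower of 14 (3 lower and 1 higher over the list alone; 0.365, estimated 0.783): Jund (-0.20), Junb (-0.08) and Egr2 (-0.43). Tissue residency had Cd69 (0.29) and Rgs1 (0.15) higher and Prdm1 (-2.22, from -3.02 in library 1 to -1.10 in library 2) lower of 8 (2 and 2 over the list alone; 0.808, estimated 0.857), with a median of -0.04 though the test pointed up. Survival had 2 higher and 3 lower of 8, the lower ones Bcl2a1d (-0.37), Bcl2a1b (-0.19) and Bcl2l1 (-0.40) (4 and 3 over the list alone; 0.598, estimated 0.783), with a median of 0.03 though the test pointed down. Heat-shock stress had Hspa1a (1.00) and Dnaja1 (0.13) higher and Hsp90aa1 (-0.18) lower of 8 (2 and 3 over the list alone; 0.598, estimated 0.800). CD8 identity had 3 higher, Cd8b1 (0.15) and Cd2 (0.13) among them, and Cd8a (-0.10) lower of 10 (5 and 2 over the list alone; 0.372, estimated 0.783).

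Few genes of other cell types passed with Tcf7. The myeloid list (6 tested) and the dendritic list (3 tested) had 0 called genes, also over each list alone (camera adjusted p = 0.694 and 0.180, adjusted p = 0.800 and 0.783 with an estimated correlation). Ikzf2 (0.40) was higher and Cd4 (-2.44) lower (0.875; 1 and 1 adjusted over the list alone, estimated 0.942). Ighm (0.74) and Pecam1 (0.65) were higher, Eomes and Cd79b did not pass, and no melanoma or red blood cell gene was tested. Which genes were called depended on the random thinning: 10 further draws called 1726 to 2323 genes, and 787 of the 1794 calls came back in every draw (371 higher, 416 lower), which left out Junb, Egr2, Tyrobp, Rgs1, Irf7, Rsad2, Bcl2l1, Hspa1a, Dnaja1, Cd8a and Cd2. Fits without the block called 155 higher and 118 lower, and DESeq2 115 and 151.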

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

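The tests of shared barcodes, of RNA from other lineages and of wrong hashtag calls were chosen only after the result was seen, while those of sex, depth and the confounded label were set after the files were read but before the genes were compared. The median ratios below were not among the values named in advance.

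The libraries shared 2805 barcodes, 59.0% of those in library 1 and 51.6% of those in library 2, and the comparisons used them in library 1 alone. A shared barcode in library 2 held a median of 25.2% of its UMIs in library 1 (5th to 95th percentile 24.1 to 26.2), and 2454 of 2454 with a hashtag in both had the same one. The tables argue against different cells that drew the same barcode: the paired profiles correlated at a median of 0.705 over 8556 genes, above the highest of 100 random pairings within hashtags (0.592). Counting of the same droplets in both libraries may explain the sharing, since 98.8% of ratios lay within 10% of the median, against at most 14.4% in random pairings. All 1925 barcodes in the deepest of 4 depth classes of library 1 were shared against 21.6% in the shallowest. In 15 shared barcodes library 2 held more UMIs. How molecules could come to be in both libraries, and in which direction, was not tested, nor was any biological explanation.

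TAM+-labelled and TAM- T cells differed in 1950 genes, with Gzmk and Pdcd1 higher and Ccr7 and Tcf7 lower. The tables argue against the sex of the cells as the whole cause, judged on cells with Y-linked transcripts and no Xist. Over the 1898 called genes with a value there, the median ratio of fold changes was 0.989. Of the called named genes 93.2% (41 of 44) stayed called in the same direction, but a naming rule that picks large folds and small p favours this. Of all 1950 calls 69.3% (1352) stayed. Depth is argued against as the whole cause too, with the same limit, since 86.4% of the named genes (38 of 44) stayed called after thinning. Of all 1950 calls only 535 stayed, as thinning removes counts. The 1740 that still had a value kept a median ratio of 0.996 (quartiles 0.747 and 1.26). RNA from other lineages is argued against as the whole cause as well. Of the genes called higher, 21.5% (191 of 890) were higher still in those lineages, and Lyz2 stood at 0 CPM (upper limit 2.00). But Siglech at 6.58 CPM in the exhausted-like cells leaves a trace of dendritic RNA open. Tamoxifen and the sort gate change with the label, and the hosts and the time of sampling may. None of these can be told apart from the label, because 0 further populations with the TAM+ label exist to part them. The deletion of Nr4a1 and Nr4a2 that the design names stays open, untested.

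Of the cells with the TAM+ hashtag, 46.8% in library 1 and 58.6% in library 2 lay in dendritic, myeloid or NK clusters, a signal in cells that no comparison used, although the protocol describes a sort of T cells. A related pattern was the 58 TAM+-labelled T cells outside the terminally exhausted-like cluster. Wrong hashtag calls of TAM- cells could place such cells there, but at the TAM- level they would hold 19.8 Xist UMIs, while 0 were seen, with an exact Poisson 95% upper limit of 3.69. The tables thus argue against wrong calls as the source of all 58, and cells of the TAM+ sort that resemble the other populations stay open.

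The Tcf7-detected against undetected difference itself differed between TAM- and CD8 T cells for 47 of 10333 genes in an edgeR interaction test, 13 higher and 34 lower in TAM-. The chemokine gene Ccl5 was higher in Tcf7-detected CD8 cells (log2 0.50, SE 0.04) and lower in Tcf7-detected TAM- cells (-1.36, SE 0.05), a difference of -1.85 (edgeR adjusted p = 4.22e-27). The chemokine receptor gene Ccr2 behaved alike (0.57 in CD8 and -0.93 in TAM-, a difference of -1.50), and Prf1 stood at -0.21 in CD8 and -1.29 in TAM-. This test was chosen after the data were seen, and the thinning draw was not varied in it.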

How the results depend on the processing

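The alternatives chosen only after seeing the data were shared barcodes kept, every cell thinned, male cells only, clusters named cycling left out in the comparisons of populations, the shallow cluster or the highest Scrublet scores left out, the Tcf7 comparison within populations, the further thinning draws, and every alternative for TAM- against CD8. Of 3453 alternative values, 2991 stayed (the same call and direction, a count within 1.5-fold, or a share or fold change within its spread), 244 were weaker, 28 stronger, 171 moved and 19 reversed. Leaving out a library made 134 of the 171 moved. Unless a cause is given, the cause was not tested.

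Counts of called genes moved as follows. DESeq2 called 474 higher and 476 lower genes in TAM+-labelled against TAM- cells (890 and 1060 as reported), 781 and 816 in TAM- against CD8 (1484 and 1490), and 115 and 151 in Tcf7-detected against undetected cells (800 and 994), where it gave an adjusted p to 2551 of 11362 genes. Thinning every cell, which leaves fewer counts and fewer genes tested, gave 250 and 327, and 959 and 939. Other lineages kept gave 1972 higher in TAM+-labelled cells, by construction with the RNA of those cells. Shared barcodes kept gave 1458 and 1663. Male cells only, which are fewer, gave 952 higher in TAM- against CD8, and library size only, in the same comparison, gave 2878 and 891. Tcf7 classes compared within populations gave 484 and 574, within CD8 416 and 451, and within TAM- 42 and 67.

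With the library as a block, TAM- against CD8 had 2408 higher and 2425 lower genes, and the 2974 reported calls were all among them. The block passed tissue residency there (0.0205) and dropped interferon response (0.133) and myeloid (0.187). Without the block, the Tcf7 comparison had 155 and 118 called genes, and its NK-receptor list passed (0.00947). Blocking changed no other list call. Among named genes, the block added calls for Tpi1, Pgk1, Hsp90aa1 and Hspa8 in TAM+-labelled against TAM- cells and for Cd3d in TAM- against CD8, and 20 of the 51 called in the Tcf7 comparison did not pass without it: Nr4a1, Jund, Junb, Egr2, Klrd1, Cd69, Rgs1, Rrm2, Mcm3, Tyms, Rsad2, Ldha, Bcl2a1d, Bcl2a1b, Bcl2l1, Hsp90aa1, Dnaja1, Cd8b1, Cd8a and Cd2. With an estimated correlation, 0, 0 and 0 T cell lists passed in the 3 comparisons (6, 9 and 6 as reported). The smallest camera adjusted p was 0.280, 0.252 and 0.528, and 2, 3 and 0 had an unadjusted camera p under 0.05. So few sums leave that variant little power, so it cannot decide on the calls.

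Genes that reversed in TAM+-labelled against TAM- cells did so with other lineages kept: Nr4a2 (-0.10), Ifitm2 (1.56), Fos (1.76), Zeb2 (0.60), Usp18 (0.82), Isg15 (1.73), Cd2 (-0.11) and Cd3g (-0.33). In the Tcf7 comparison, unthinned classes reversed Rgs1 (-0.21), Tyms (0.0816), Irf7 (-0.00647), Rsad2 (-0.16) and Cd2 (-0.0597). Thinning to 1000 UMIs reversed Rsad2 (-0.60), as did 1 thinning draw (-0.50). Other lineages kept reversed Irf7 (-0.000751), clusters named cycling left out Junb (0.0200), and TAM- cells alone Klrd1 (-0.0737) and Rgs1 (-0.0302). No named gene reversed in TAM- against CD8.

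The 10 further thinning draws called 870 to 1149 higher and 856 to 1281 lower genes, and each kept 68.2% to 78.3% of the 1794 reported calls. Calls seen in every draw numbered 787, and 78 came back in none.

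Shares of T cells moved with clustering, since a resolution merges or splits clusters. In libraries 1 and 2 the progenitor-exhausted-like share was 45.5% and 44.8% at resolution 0.3, 17.9% and 18.0% at 1.0, 29.2% and 27.7% with all deposited barcodes, and 23.8% and 20.2% with the strict filter. The cycling-like share was 48.0% and 47.8%, and 3.75% and 3.37%, at those resolutions, 20.8% and 18.8% with the strict filter, and 31.3% and 33.1% with doublets kept. The difference between TAM+-labelled and TAM- cells in the progenitor-exhausted-like share (-3.10 points) was 0.68 at resolution 0.3, 2.85 at 1.0, -10.8 as a Tcf7 share, and -7.30 to 1.09 leaving out a library. The exact permutation test cannot pass a threshold with 2 libraries. The Tcf7-detected share of T cells followed depth: 11.8% and 12.8% at 1000 UMIs, 30.7% and 29.1% at 4000, and 47.7% and 42.9% unthinned.

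Fold changes of named genes moved by more than their SE without library 1 for 32 of 50, 16 of 53 and 33 of 52 genes in the 3 comparisons, and without library 2 for 16, 10 and 27. Every called named gene kept its direction in each library alone, which the naming rule had required of the 8 highest and 8 lowest. Moves of over 1.5-fold were seen for 8, 0 and 4 genes. These were Nr4a1, Igkc, Ccl9, Xist, Ccr7, Nfkbid, Ifit2 and Bnip3 in TAM+-labelled against TAM- cells, and Gzma, Gzmc, Prdm1 and Rsad2 with Tcf7. The single-library values are differences of log2 CPM with a prior of 2 counts and not refits. Part of a move can therefore come from the estimator. Xist stood at -7.94 and -8.03 in libraries 1 and 2 alone, against -11.97 in the fit of both. Counts of called genes have no leave-one-out value, since 1 sum per group allows no test. Depth limits the 63 TAM+-labelled T cells of library 2 most, with 427730 UMIs.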

Other observations

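No hypothesis is offered here, and these values were looked up after the comparisons were seen. Igkc stood at 206 CPM (95% Poisson interval 184 to 230) in the 173 TAM+-labelled cells of the terminally exhausted-like cluster, where Siglech stood at 6.58 CPM (3.16 to 12.1). In the Siglech-led dendritic cluster of the same hashtag Igkc stood at 431 CPM (373 to 494) and Siglech at 1627 CPM (1513 to 1746). The 11 TAM+-labelled cells of the cluster led by Utf1 held 15 Igkc UMIs, and the 18 in the progenitor-exhausted-like cluster held 0 (upper limit 66.8 CPM).

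Tcf7 differed within the TAM+-labelled T cells. It stood at 272 CPM (152 to 448) in the 18 cells of the progenitor-exhausted-like cluster, which Tcf7 helps to define, and at 7.24 CPM (3.61 to 13.0) in the terminally exhausted-like cluster. Gzmk stood at 561 CPM (381 to 797) and 595 CPM (557 to 635) in these cells. Among TAM- cells of the progenitor-exhausted-like cluster Gzmk stood at 6.16 CPM (3.37 to 10.3), and among the 26 TAM- cells of the terminally exhausted-like cluster at 353 CPM (272 to 451).

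Xist marks cells from female mice. A Xist UMI was seen in 12.8% and 14.1% of CD8 and in 19.96% and 18.6% of TAM- T cells of libraries 1 and 2. It was seen in 0 of 168 TAM+-labelled T cells, with a 95% Clopper-Pearson upper limit of 2.17%, and in 0 of 63, with a limit of 5.69%. A UMI of a Y-linked gene was seen in 45.4% and 36.8% of CD8, 63.8% and 50.2% of TAM-, and 58.9% and 49.2% of TAM+-labelled T cells. The OT-I segment Trbv12-1 was seen in 95.3% of CD8, 96.7% of TAM- and 90.0% of TAM+-labelled T cells.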
